A study of Mus musculus with 3 samples.

How the data were processed

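Polyadenylated RNA of 3 samples of 5TGM1.BRE cells, an engraftable bortezomib-resistant mouse myeloma line, was sequenced. Per the labels' protocols, the cells grew in IMDM with 20% serum and 10 nM bortezomib, drug was withdrawn at least 72 h before extraction, and RNA came from 10000000 cells per sample with a column kit. The deposited tables hold raw counts per gene, 1 table per sample, with 24467 gene symbols each and no header. Per the submitters' processing notes, the authors used bcl2fastq, cutadapt 4.2 and STAR, with the mouse genome mm10. The counting program, its annotation and strand setting, and the STAR version are not given in the sources used here, so overlapping genes, antisense genes and genes with near-identical copies are uncertain. Depth was 62303493, 45705994 and 59402218 counts for replicates 1, 2 and 3, and a count of 0 allows up to 3 counts, or 0.0482, 0.0656 and 0.0505 CPM (counts scaled to a library total of 1000000), and 0.0179 CPM over all 3. Such limits cover counting error only, since PCR copies are not independent molecules.

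All 3 samples formed 1 group by their titles. The cell type label of replicate 1 lacks the phrase on culture in bortezomib that replicates 2 and 3 carry, while its growth protocol and title are the same. Chi-square tests of homogeneity were run over genes with at least 20 counts in the pair. They gave 4.0, 65.1 and 44.4 per degree of freedom for replicates 1 and 2, 1 and 3, and 2 and 3. Each pair thus differed beyond the noise of independent counts, and the 3 libraries were kept apart. PCR copies are not independent, so part of this excess may come from them. Pearson correlations across genes of log2(CPM + 1) were 0.9997, 0.9984 and 0.9987, and Spearman correlations 0.9714, 0.9678 and 0.9668. With 1 group, no comparison between groups was made. Genes at 1 CPM or more in all libraries numbered 10016, 16272 had a count in any library and 8195 had none.

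Gene lengths, GC content and positions came from GENCODE M21 (GRCm38, the assembly of mm10). Of the symbols, 23688 matched directly, 466 through an older symbol and 313 not at all, and 98.72% received a length. Immunoglobulin constant and mitochondrially encoded genes were not analysed here, nor was Trac, so 33 of 35 fixed gene lists and 13 of 16 fixed ratios have values. Rigi was also listed under its older symbol Ddx58 and was analysed under that symbol.

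Counts were divided by the library total and scaled to 1000000 to give CPM. A list's level is the median over members of the mean log2(CPM + 1), set against 10000 random lists of the same size among genes with a count. A list can hold members at 0 that no random list could, which lowers its percentile. Ratios within a library used counts per kilobase of union exon length and an exact two-sided sign-flip permutation test. For tests across genes, edgeR 4.0.16 in R 4.3.3 was used with TMM scaling and filterByExpr, which kept 11308 genes. The quasi-likelihood test set each library against the other 2 with 1 residual degree of freedom and Benjamini-Hochberg adjustment at 0.05. The SE of a fold change is its size divided by the square root of the test's F statistic. It reflects the spread between the other 2 libraries, moderated over all genes, and not that of a replicated difference. It can thus be small for a gene that differs between those 2 libraries. For example, Hist1h2ab had 32 and 255 counts in replicates 1 and 2, and an SE of 0.13 for replicate 3. The common biological coefficient of variation came from an intercept-only fit. A chi-square test per gene, which takes counts as independent, found 7113 of 11308 genes that varied beyond counting noise. On simulated data with a 3% coefficient of variation, the test recovered 64.2, 88.1 and 92.4% of genes changed 1.25-, 1.5- and 2-fold for replicate 3, with few of the unchanged genes called. The simulation had 200 changed genes and no trend on length, so it does not show how reliable the calls on the real libraries are.

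The lists, ratios, tests and the rule for named genes were set before the data were examined. The rule names the 10 most abundant genes, the 3 highest members of every list and up to 3 members at 0 counts, the members of the ratios, a fixed set of myeloma and stress genes, and for each library the 5 largest rises and 5 largest falls with a mean log2 CPM of at least 1. Some genes that the rule names are not reported here. Other genes named were chosen after their values were seen. Alternatives were RLE scaling, no scaling, no filter on low counts, DESeq2 1.42.0, pseudocount 0.1, values with or without length, other detection limits, and leaving out each replicate. Removal of trends on length and GC content (loess, span 0.3), thinning to equal depth, random lists matched on length or on length and expression, and the longest transcript as the length were chosen after seeing the data. Python 3.11.15 with pandas 2.3.3 and SciPy 1.17.1 was used for the rest.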

Results

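Gene expression was measured by sequencing of polyadenylated RNA in 5TGM1.BRE cells, a bortezomib-resistant mouse multiple myeloma line. Bortezomib is an inhibitor of the proteasome, the complex that degrades ubiquitin-tagged proteins, and is used to treat myeloma. The parental 5TGM1 line arose from a myeloma that developed spontaneously in C57BL/KaLwRij mice, and the resistant cells studied here were recovered from the bone marrow of such mice, where they had engrafted. They were kept in 10 nM bortezomib and taken off the drug at least 72 h before RNA was extracted from 10000000 cells per sample. There were 3 libraries in 1 group, with 62303493, 45705994 and 59402218 gene counts for replicates 1, 2 and 3. The sensitive parental line and a resistant line that was not recovered from mice were not analysed here, so levels are given within the engraftable resistant cells and no change on resistance was measured. The labels do not say whether the replicates were separate cultures. The SDs below thus measure the spread between these 3 samples, which may be technical, and the p-values hold for these samples only.

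The cells carried the transcripts of plasma cells and few of those of earlier B cells. Of 18 plasma cell genes, 12 were at 1 CPM (counts scaled to a library total of 1000000) or more in all 3 libraries, with a list median of 103 CPM that lay above all 10000 random lists of the same size. Genes named as leading or highest in a list here are so by CPM, which is not corrected for gene length. Pou2af1, a B-lineage coactivator, was at 1218 ± 36.7 CPM (SD, n = 3), and Xbp1, a transcription factor of secretory cells, at 1180.0 ± 48.3 CPM (SD, n = 3). Irf4, a transcription factor on which myeloma cells depend, was at 978 ± 45.1 CPM, Prdm1, the regulator of plasma cell differentiation, at 194 ± 22.7 CPM, and Sdc1, which encodes the plasma cell surface protein CD138, at 539 ± 8.62 CPM (SD, n = 3 for each). Of 18 B cell genes, 5 reached 1 CPM in all libraries and the list median was 0.0779 CPM, at percentile 0.65 of random lists. Cd74, the invariant chain of MHC class II, was at 604 ± 39.6 CPM, Cd37 at 105 ± 2.28 CPM and Cd79b at 92.0 ± 6.39 CPM (SD, n = 3 for each). Pax5, which maintains B cell identity, had 40, 20 and 5 counts, and Bcl6 and Cr2 had none in any library. The summed level of Prdm1, Irf4 and Xbp1 per kilobase exceeded that of Pax5, Bcl6 and Bach2 by 13.96 ± 1.2 on the log2 scale (SD, n = 3), a ratio that rests on the few Pax5 and Bach2 counts and was 12.77 without lengths. By edgeR's quasi-likelihood test, used for all comparisons between libraries, 5 plasma cell genes were higher and 5 lower in replicate 3 than in the other 2 libraries, with the same numbers adjusted over the list alone, and 2 higher and 3 lower once the trend on transcript length was removed.

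Some transcripts of myeloma surface proteins were at or near 0. Cd38, whose product is a plasma cell antigen in humans, lies on chromosome 5 at 43868553 to 43912375 on the plus strand (GRCm38). It had 0 counts in all 3 libraries, which allows a level of up to 0.0179 CPM over the 167411705 counts of all libraries. Normal mouse plasma cells were not measured here, so whether this level is unusual for them was not tested. Tnfrsf17, which encodes the B cell maturation antigen, was at 0.582 ± 0.145 CPM (SD, n = 3), with 41, 19 and 40 counts. Slamf7 was at 77.3 ± 7.62 CPM and Jchain, which joins immunoglobulin polymers, at 312 ± 22.0 CPM (SD, n = 3 for each). Derl3 and Fkbp11, both linked to secretion, had means of 0.828 and 0.409 CPM, with Derl3 at 1.05 CPM in replicate 2. Sdc1 lies on chromosome 12 at 8771323 to 8793715 on the plus strand. Immunoglobulin constant genes were not analysed here.

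Markers of other bone marrow cells were near the detection floor, apart from a few genes. None of 14 T and NK cell markers reached 1 CPM in all libraries, and the highest by CPM, Lck, was at 0.148 ± 0.0725 CPM (SD, n = 3). Of 18 myeloid markers, 2 did: Ctss, a lysosomal protease, at 842 ± 53.1 CPM and Cd68, a lysosomal membrane protein, at 473 ± 15.3 CPM (SD, n = 3 for each). The neutrophil genes S100a8 and S100a9 had 0 counts in every library. Itga2b, at 16.2 ± 1.21 CPM (SD, n = 3), was the 1 gene of 13 erythroid and megakaryocyte markers above the limit. Pecam1, at 5.32 ± 0.442 CPM, was the 1 of 18 stromal and endothelial markers, and Flt3, at 2.14 ± 0.316 CPM, the 1 of 8 stem and mast cell markers (SD, n = 3 for each).

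**Figure D1:**
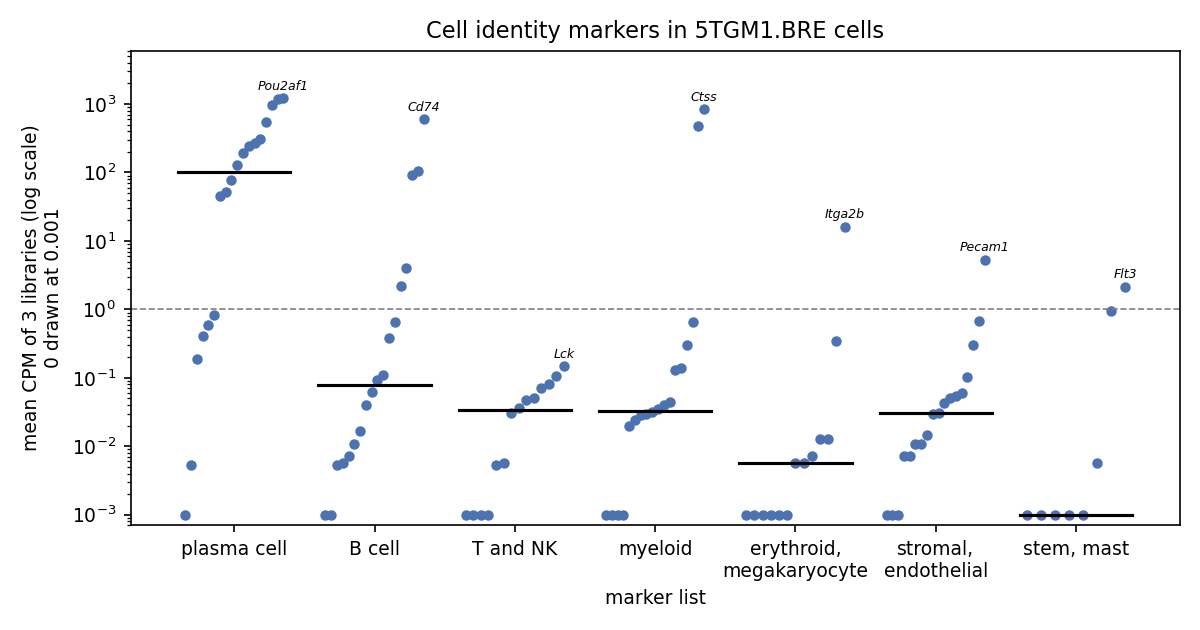
Mean CPM over the 3 libraries (log scale) of each gene in the marker lists, with 1 point per gene, genes at 0 drawn at 0.001, a bar at the list median and a dashed line at 1 CPM. The plasma cell median of 103 CPM lies above the line and the medians of the other 6 lists lie below it, with single abundant genes such as Cd74 and Ctss named.

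The strain of origin was checked with Samsn1, an adaptor gene that C57BL/KaLwRij mice are known to lack. Samsn1, on chromosome 16 at 75858793 to 76022281 on the minus strand, had 0, 0 and 2 counts in replicates 1, 2 and 3. Xist, the X-inactivation RNA, had 82, 45 and 57 counts, or 1.09 ± 0.199 CPM (SD, n = 3). The Y-linked genes Eif2s3y, Kdm5d and Uty had none, and Ddx3y had 0, 1 and 2 counts. All 7 genes listed for possible loss or retroviral insertion were at 1 CPM or more, among them Mtap at 152 ± 2.18 CPM, Xpr1 at 74.2 ± 10.1 CPM and Trp53 at 147 ± 4.2 CPM (SD, n = 3 for each).

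The proteasome, the target of the drug, was expressed throughout. All 11 structural subunits of the 20S core were at 1 CPM or more, with a median of 397 CPM, above all random lists. The highest by CPM were Psmb4 at 578 ± 70.6 CPM, Psma7 at 575 ± 71.1 CPM and Psma4 at 445 ± 44.9 CPM (SD, n = 3 for each). All 22 genes of the 19S regulatory particle list passed the limit with a median of 289 CPM. The list was led by CPM by Psmd1 at 532 ± 21.5 CPM, Psmd2 at 504 ± 25.3 CPM and Psmd8 at 492 ± 38.4 CPM (SD, n = 3 for each). It also holds Psmd5, Psmd9 and Psmd10, which encode assembly chaperones of the particle, at means of 108.7, 55.7 and 47.6 CPM. Per kilobase of exon, Psma6 and Psmc1 led the 20S structural and 19S genes instead. Per kilobase, the geometric mean of the 20S structural genes exceeded that of the 19S genes by 1.12 ± 0.075 on the log2 scale (SD, n = 3), a 2.17-fold difference found in 3 of 3 libraries. The chaperone genes lower the 19S mean, and the ratio without them was not computed.

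Psmb5, which encodes the catalytic subunit that bortezomib binds most strongly, was the least abundant of the constitutive catalytic genes by CPM. It was at 58.0 ± 5.60 CPM (SD, n = 3), against 294 ± 33.7 CPM for Psmb6 and 355 ± 27.9 CPM for Psmb7 (SD, n = 3 for each). Psmb5 lies on chromosome 14 at 54614119 to 54618022 on the minus strand. Of the immunoproteasome genes, which replace these subunits in immune cells, Psmb8 was at 209 ± 20.6 CPM, Psmb10 at 46.7 ± 7.22 CPM and Psmb9 at 37.4 ± 4.38 CPM (SD, n = 3 for each). Per kilobase, the constitutive catalytic genes together exceeded the immunoproteasome genes 3.28-fold, with a log2 ratio of -1.71 ± 0.034 (SD, n = 3). Psmb9 was 15.4-fold below Psmb6 per kilobase, 7.87-fold without lengths and 23.5-fold with the longest transcript as the length. Psmb10 was 3.81-fold below Psmb7 per kilobase and 7.65-fold without lengths. The ratio of Psmb8, on chromosome 17 at 34197721 to 34201454 on the plus strand, to Psmb5 was -0.06 on the log2 scale per kilobase, but 1.85 without a length correction and 0.76 with the longest transcript as the length, so its direction depends on the length taken for each gene. For each of these ratios the exact two-sided sign-flip permutation test gave p = 0.25 over n = 3 libraries (0.271 after Benjamini-Hochberg adjustment over 13 ratios), the smallest p that 3 libraries allow. The other ratios given here reached the same p, except that of Itga4 to Itgal. These proteasome genes moved with replicate 3: all 11 structural, all 3 constitutive and all 3 immunoproteasome genes were higher there than in the other 2 libraries, both over all genes and adjusted over the list alone, with median log2 differences of 0.23, 0.27 and 0.32. Against random lists matched on expression and transcript length, these medians lay at percentiles 43.74, 46.99 and 99.22. Of the 22 genes of the 19S particle, 13 were higher there, or 15 higher and 1 lower adjusted over the list alone, at percentile 37.08 of such matched lists.

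**Figure D2:**
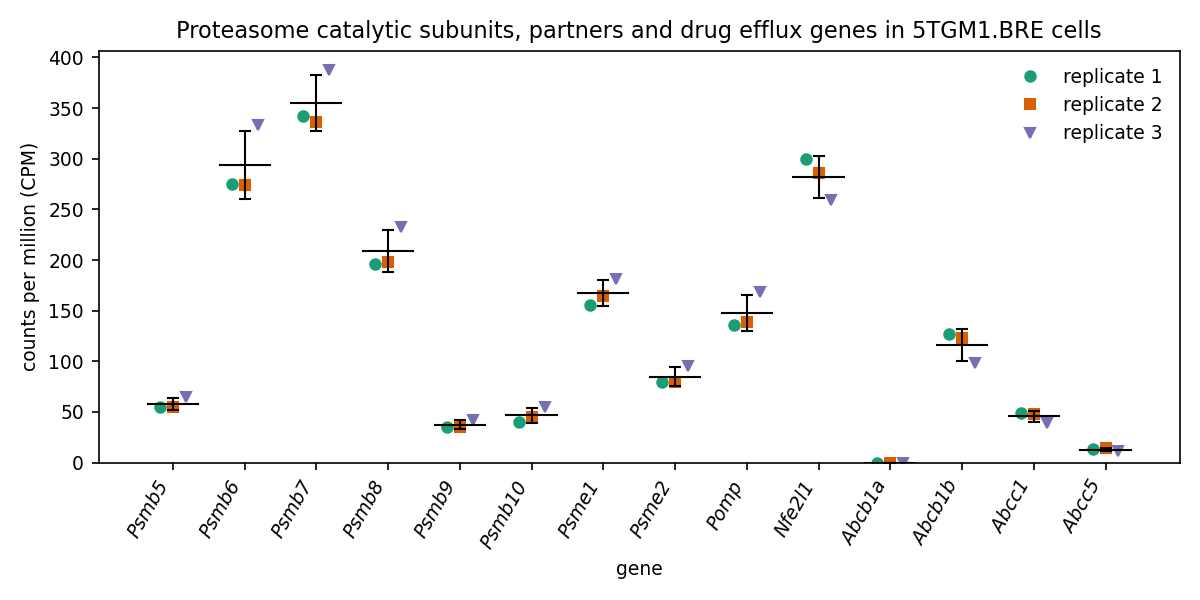
CPM of proteasome catalytic subunits, activators, the assembly chaperone Pomp, the transcription factor Nfe2l1 and drug efflux genes, with 1 point per library, the horizontal bar at the mean and error bars of 1 SD (n = 3). Psmb5 at 58.0 CPM lies below Psmb6 and Psmb7, Abcb1b at 116 CPM is the highest efflux gene, and replicate 3 is the highest library for each catalytic subunit.

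Proteasome activators and assembly factors were all expressed, at a median of 119 CPM over 10 genes. Psme4 was at 295 ± 47.2 CPM, Psme3 at 265 ± 18.6 CPM, Psme1 at 167 ± 12.9 CPM and Pomp, a chaperone of 20S assembly, at 148 ± 17.6 CPM (SD, n = 3 for each). In replicate 3, 7 of these 10 genes were higher and 2, Psme3 and Psme4, were lower than in the other 2 libraries, with the same numbers adjusted over the list alone. Nfe2l1, the transcription factor that induces proteasome genes when the proteasome is inhibited, was at 282 ± 20.9 CPM, and Nfe2l2, the regulator of antioxidant genes, at 99.2 ± 1.08 CPM (SD, n = 3 for each). All 16 ubiquitin genes and receptors passed 1 CPM. Rps27a, which encodes a ubiquitin fusion, was at 1961 ± 242 CPM and Sqstm1, an autophagy receptor for ubiquitinated proteins, at 1051 ± 15.9 CPM (SD, n = 3 for each).

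Most genes of the stress lists were expressed, while a few, such as Hspa1a and Srxn1, were at or near 0. Of 26 genes of endoplasmic reticulum stress and secretion, 25 passed 1 CPM, with the highest median of the stress lists, 533 CPM. Hsp90b1 was at 4772 ± 121 CPM, Hspa5, the main chaperone of the endoplasmic reticulum, at 2396 ± 4.35 CPM and Pdia4 at 1912 ± 50.6 CPM (SD, n = 3 for each). Of 15 genes of the heat shock list, which holds cytosolic chaperones and the mitochondrial chaperonin genes Hspd1 and Hspe1, 12 passed, led by Hsp90ab1 at 4093 ± 89.8 CPM, Hspa8 at 1426 ± 74.6 CPM and Hspd1 at 1037 ± 51.1 CPM (SD, n = 3 for each), whereas Hspb1 had 0 counts and the heat-inducible Hspa1a had 1, 2 and 0 counts. Hspa1a has a near-identical copy, Hspa1b, so its counts are uncertain. Of 16 genes of the integrated stress and amino acid response, 14 passed. Psat1 was at 732 ± 50.8 CPM, Shmt2 at 707 ± 4.64 CPM, Atf4 at 685 ± 60.5 CPM and the Atf4 target Ddit3 at 15.8 ± 2.03 CPM (SD, n = 3 for each), while Vldlr had 0 counts. Of 18 antioxidant genes, 16 passed. Txn1 was at 1184 ± 158 CPM, Prdx1 at 1039 ± 104 CPM and Sod1 at 580.1 ± 78.8 CPM (SD, n = 3 for each), while Nqo1 was at 0.144 CPM and Srxn1 had 0 counts. All 16 autophagy genes passed, led by Lamp1 at 868 ± 21.2 CPM, Lamp2 at 584 ± 19.2 CPM and Gabarap at 229 ± 18.9 CPM (SD, n = 3 for each).

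Of 8 drug efflux transporters, 3 were expressed. Abcb1b, 1 of the mouse genes for P-glycoprotein, a pump that exports many drugs, was at 116 ± 15.4 CPM, Abcc1 at 45.6 ± 5.51 CPM and Abcc5 at 12.9 ± 1.69 CPM (SD, n = 3 for each). Abcb1b lies on chromosome 5 at 8798147 to 8866315 on the plus strand. The paralog Abcb1a had 3, 2 and 3 counts, Abcg2 had 3, 1 and 3 counts and Abcc4 had 0. Abcc1 was 4.81-fold below the sum of Abcb1a and Abcb1b per kilobase, at a log2 ratio of -2.27 ± 0.019 (SD, n = 3), and 2.55-fold below without lengths. All 3 expressed transporters were lower in replicate 3 than in the other 2 libraries, with a median log2 difference of -0.30 and the same count adjusted over the list alone. With the trend of the log2 fold change on transcript length removed, 1 of the 3, Abcb1b, stayed lower.

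Among the regulators of apoptosis, Mcl1 was the most abundant survival gene. It was at 486 ± 12.8 CPM, against 201 ± 9.69 CPM for Bcl2l1, 50.7 ± 1.45 CPM for Bcl2l2 and 14.2 ± 0.759 CPM for Bcl2 (SD, n = 3 for each), and Bcl2a1a, Bcl2a1b and Bcl2a1d had 0 counts. The Bcl2a1 genes are near-identical copies of each other, so their counts are uncertain. Per kilobase Mcl1 exceeded Bcl2 91.5-fold (log2 6.51 ± 0.10, SD, n = 3) and Bcl2l1 3.24-fold (log2 1.70 ± 0.052, SD, n = 3). Without lengths the excess over Bcl2 was 34.1-fold, and with the longest transcript that over Bcl2l1 was 1.81-fold. Of 11 proapoptotic genes, 8 passed 1 CPM, led by Pmaip1, which encodes the MCL1-binding protein NOXA, at 418 ± 9.92 CPM, Bax at 101 ± 14.0 CPM and Bak1 at 99.8 ± 5.18 CPM (SD, n = 3 for each), and Hrk had 0 counts.

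Oncogene and cell cycle transcripts were abundant. Of 29 myeloma oncogenes and tumour suppressors, 24 passed 1 CPM. Ccnd2, a G1 cyclin, was at 539 ± 73.2 CPM, Myc at 464 ± 7.70 CPM and Cdkn1a, the p21 inhibitor of cyclin-dependent kinases, at 266 ± 11.7 CPM (SD, n = 3 for each). Myc lies on chromosome 15 at 61985391 to 61990374 on the plus strand. Ccnd3 was at 67.3 ± 2.96 CPM, Ccnd1 at 7.29 ± 0.803 CPM and Cdkn2a at 4.01 ± 0.301 CPM (SD, n = 3 for each), and Mycn had 0 counts. Per kilobase Ccnd2 exceeded Ccnd3 7.42-fold (log2 2.89 ± 0.27, SD, n = 3) and Ccnd1 36.9-fold (log2 5.21 ± 0.04, SD, n = 3). With the longest transcript the excess over Ccnd3 was 4.85-fold, and without lengths that over Ccnd1 was 73.8-fold. Of 28 cell division genes, 27 passed, led by Top2a at 653 ± 92.6 CPM, Mki67 at 609 ± 92.6 CPM and Rrm2 at 491 ± 5.97 CPM (SD, n = 3 for each), while Cdk6 was at 0.0399 CPM. The oncogene list had 3 genes higher and 9 lower in replicate 3, with the same numbers adjusted over the list alone, and 8 higher and 1 lower once the length trend was removed.

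Of 26 genes for homing and adhesion to bone marrow, 14 passed 1 CPM. Cd44, a hyaluronan receptor, was at 672 ± 21.1 CPM, Itga4, the alpha chain of the VLA-4 integrin, at 642 ± 122 CPM and its partner Itgb1 at 636 ± 65.6 CPM (SD, n = 3 for each). Cxcr4, the receptor for the marrow chemokine CXCL12, was at 80.2 ± 2.51 CPM (SD, n = 3) and lies on chromosome 1 at 128588199 to 128592293 on the minus strand. Itgal was at 290.5 ± 29.7 CPM (SD, n = 3). The log2 ratio of Itga4 to Itgal was 0.04 ± 0.14 per kilobase (SD, n = 3), 1.13 without lengths and 0.23 with the longest transcript, so whether the levels differ depends on the length taken. The exact sign-flip permutation test gave p = 0.75 per kilobase and could not have gone below 0.25 with n = 3. Itgb1 exceeded Itgb7, the alternative beta chain, 621-fold (log2 9.28 ± 0.48, SD, n = 3). Cxcr3 and Ccr2 had 0 counts. In replicate 3, 4 genes of this list were higher and 8 lower than in the other 2 libraries, with the same numbers adjusted over the list alone, and 2 higher and 5 lower once the length trend was removed. Itga4 was among the lower genes, at a log2 fold change of -0.47 that became -0.17 with the trend removed.

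Few secreted factors acting on bone and vessels were transcribed. Of 23 genes, 6 passed 1 CPM, and the list median of 0.0129 CPM lay below all 10000 random lists. Those lists held only genes with a count, while 6 of the 23 genes were at 0, which in part sets this place. Vegfa was at 66.4 ± 2.68 CPM, Vegfb at 40.6 ± 2.52 CPM and Spp1, which encodes osteopontin, at 18.0 ± 1.32 CPM (SD, n = 3 for each). Dkk1, an inhibitor of bone formation, Sost and Tnfsf11, which encodes the osteoclast factor RANKL, had 0 counts in all 3 libraries, which allows up to 0.0179 CPM for each. Of the 8 genes of this list that were tested in replicate 3, 4 were higher there, or 7 adjusted over the list alone, and 1 was higher once the length trend was removed.

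The replicates were compared with one another in turn, each library against the other 2, to see how far a level could depend on 1 library. Replicate 3 stood apart: the biological coefficient of variation was 2.57% without it, against 10.6% without replicate 1 and 12.1% without replicate 2. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 5834 of 11308 tested genes were called, 2803 higher and 3031 lower. These calls set 1 library against the small spread of replicates 1 and 2, which may be technical, so their number is not that of a replicated difference. DESeq2's Wald test called 3184, 1374 higher and 1810 lower. Ribosomal protein genes were higher in replicate 3, 28 of 29 listed genes (29 adjusted over the list alone), with a median log2 difference of 0.30, and 14 were higher and 1 lower once the length trend was removed. All 81 such genes took 8.77, 9.11 and 10.8% of counts in replicates 1, 2 and 3. Among genes with a mean log2 CPM of at least 1, the largest rises in replicate 3 were Hist1h2af at a log2 fold change of 0.97 (SE 0.07), Hist1h2ab at 0.89 (SE 0.13), Cnih2 at 0.86 (SE 0.15), 5730408K05Rik at 0.84 (SE 0.12) and Ctxn1 at 0.75 (SE 0.15). The largest falls were Nrip1, a nuclear receptor corepressor, at -1.79 (SE 0.11), Pdpr at -1.74 (SE 0.15), Prrg4 at -1.35 (SE 0.10), Tnks, a poly-ADP-ribosyltransferase, at -1.35 (SE 0.08) and Ptch1, the Hedgehog receptor, at -1.32 (SE 0.09). Hist1h2ab had 32, 255 and 300 counts in replicates 1, 2 and 3. Scaled to depth, replicate 3 was not above replicate 2, so this rise comes from the low count of replicate 1. The histone genes have near-identical copies, so their counts are uncertain. The biological coefficient of variation over all 3 libraries was 9.39%.

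The log2 fold changes of replicate 3 followed transcript length. Across 11236 genes, which are not independent replicates, their Spearman correlation with length was -0.637. The trends of replicates 1 and 2 are not read as their own, because replicate 3 is in the reference of each and a trend in it alone would turn theirs the other way. The shortest decile of genes, with a median of 927 bp, had a median log2 fold change of 0.29 in replicate 3, and the longest, with a median of 8025 bp, -0.28. With the length trend removed, 3160 genes differed, 2442 of them shared with the uncorrected calls. Of the proteasome lists, 4 of 11 structural, 1 of 3 constitutive catalytic and all 3 immunoproteasome genes were then higher. Of the 19S genes, 6 were higher and 1 lower, and of the activators and assembly factors, 3 were higher and 2 lower.

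**Figure D3:**
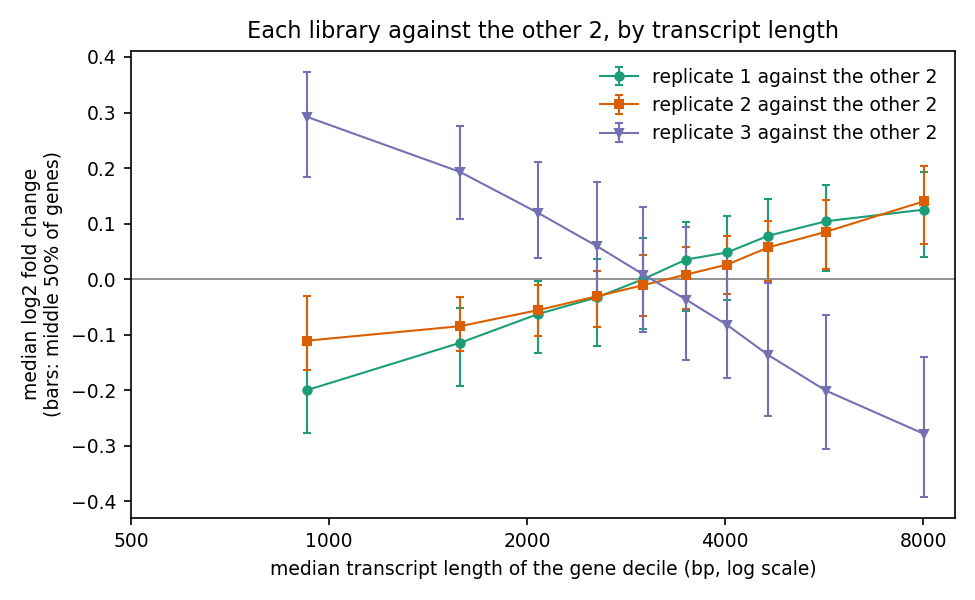
Median log2 fold change of each library against the other 2 (vertical axis) by median transcript length of the gene decile in bp (horizontal axis, log scale), with bars over the middle 50% of genes. Replicate 3 runs from 0.29 for the shortest genes to -0.28 for the longest. Replicates 1 and 2 run the other way, at -0.20 and -0.11 for the shortest genes. Replicate 3 is in the reference of each, so these courses are not read as their own.

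Replicates 1 and 2 differed from the rest in few genes. By the same test, 9 genes passed for replicate 1, 3 higher and 6 lower, and 6 passed for replicate 2, 3 higher and 3 lower. Fcer2a, the low-affinity IgE receptor of B cells, had 404, 74 and 246 counts, and was higher in replicate 1, at a log2 fold change of 1.12 (SE 0.24), and lower in replicate 2, at a log2 fold change of -1.72 (SE 0.33). Lrrc17 had 242, 1262 and 469 counts, with log2 fold changes of -2.19 (SE 0.25) in replicate 1 and 2.21 (SE 0.24) in replicate 2. Tmcc2 had 684, 2933 and 1570 counts, with -2.05 (SE 0.21) in replicate 1 and 1.76 (SE 0.21) in replicate 2. Hist1h2ab had 32, 255 and 300 counts and was lower in replicate 1 at -3.38 (SE 0.33), and Hist1h2af was lower there at -0.90 (SE 0.20), and at -0.65 and no longer called once the length trend was removed. Each library is in the reference of the others, so a gene that departs in 1 library, replicate 3 included, also shifts the others. Hist1h2af, with 1024, 1048 and 2219 counts, departed in replicate 3. For replicates 1 and 2 the spread includes replicate 3. The biological coefficient of variation was 10.6% for replicate 1 and 12.1% for replicate 2, so smaller differences would be missed. DESeq2's Wald test called 1 gene for each.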

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

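The length and GC corrections, the thinning to equal depth and the longest-transcript lengths were chosen after seeing the data. Leaving out 1 replicate moved the biological coefficient of variation between 2.57 and 12.1% and the number of genes varying beyond counting noise between 971 and 7043, both lowest without replicate 3. DESeq2 called 1, 1 and 3184 genes for replicates 1, 2 and 3, and the calls for replicate 3 came to 3160 with the length trend removed and 3122 with the length and GC trends removed. The cause was not tested for DESeq2. RLE scaling and no filter gave 5848 and 5686 genes for replicate 3. The ratio of Psmb8 to Psmb5 reversed, from -0.06 to 1.85 without lengths and 0.76 with the longest transcript, and the lengths are the difference. Without lengths, the log2 ratios became -1.27 for immunoproteasome over constitutive genes, -2.98 for Psmb9 over Psmb6, -2.93 for Psmb10 over Psmb7, 0.60 for 20S over 19S, 5.09 for Mcl1 over Bcl2, 1.27 for Mcl1 over Bcl2l1, 6.20 for Ccnd2 over Ccnd1, -1.35 for Abcc1 over Abcb1, 1.13 for Itga4 over Itgal and 9.84 for Itgb1 over Itgb7. With the longest transcript they were -1.64, -4.55, 1.19, 6.17, 0.86, 5.45, -2.01 and 0.23 for the same ratios except those of Psmb10 and Itgb7, and 2.28 for Ccnd2 over Ccnd3. Of 132 recomputed list counts, 132 stayed within 1.5 times. Of 33 list medians recomputed per kilobase, 27 moved by more than 1 SD, as did 13 with pseudocount 0.1. Leaving out 1 of 3 replicates cannot move a mean by 1 SD, so the rest of the 165 recomputed medians do not test this. RLE scaling moves all genes of a library by 1 constant, so it does not test the 87 list shifts. Leaving out a replicate from a test of 1 library against 2 leaves no residual degree of freedom. The alternatives that leave out immunoglobulin and mitochondrial genes were not run, since those genes were not analysed here. No paired analysis was possible because there is 1 group.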

Other observations

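The tests on ribosomal protein genes, on other cell types and on Fbxl5 and Prom1 were chosen after the result was seen. The 10 most abundant genes by CPM took 4.10 ± 0.0382% of counts (SD, n = 3). Eef1a1, a translation elongation factor, led at 8425 ± 458 CPM, followed by the nucleolar gene Ncl at 4796 ± 88.1 CPM, Hsp90b1, Hsp90ab1 and Rpl4 at 4026 ± 226 CPM (SD, n = 3 for each). Eef2 was at 3348 ± 412 CPM, Npm1 at 3053 ± 142 CPM, Pabpc1 at 2942 ± 154 CPM, Rplp0 at 2915 ± 217 CPM and Rpl8 at 2527 ± 287 CPM (SD, n = 3 for each). All 29 listed ribosomal protein genes passed 1 CPM, with a median of 1470 CPM.

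Of 21 genes of glycolysis and hypoxia, 18 were at 1 CPM or more, led by CPM by Pkm at 2162 ± 50.7 CPM, Ldha at 1340.0 ± 86.3 CPM and Aldoa at 1292 ± 50.9 CPM (SD, n = 3 for each). Of 17 cholesterol synthesis genes, 16 passed, among them Srebf2 at 130.3 ± 17.6 CPM and Insig1 at 114 ± 1.08 CPM (SD, n = 3 for each). The interferon response list was less abundant, with 18 of 23 genes passing and a median of 4.69 CPM, at percentile 31.43 of random lists. In that list B2m was at 2113 ± 203 CPM, Bst2 at 91.4 ± 9.25 CPM and Tap1 at 66.3 ± 1.31 CPM (SD, n = 3 for each), while Oas1a and Usp18 had 0 counts. Of 15 NF-kappaB genes, 13 passed, led by Nfkbia at 114 ± 4.93 CPM, Nfkb1 at 100.4 ± 11.7 CPM and Ikbkb at 53.8 ± 2.37 CPM (SD, n = 3 for each). Of 14 immediate early genes, 8 passed, led by Jund at 204 ± 14.2 CPM, Ier2 at 105 ± 13.1 CPM and Junb at 48.7 ± 2.63 CPM (SD, n = 3 for each), and Egr3 had 0 counts.

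Replicate 3 was called apart from the other 2 libraries in 5834 genes, 1 library against the small spread of the other 2, with medians higher for short genes and lower for long genes. Many of the calls stayed once a smooth trend on the longest annotated transcript was removed. The lengths of the transcripts expressed were not known, so these calls cannot show a cause besides length. The 77 ribosomal protein genes lay at percentile 100 of lists of other genes matched on length. Their median log2 fold change was 0.32, against 0.20 to 0.28 for those lists, whose genes were less abundant, at a median log2 CPM of 4.26 against 10.12. The fixed list of 29 lay at percentile 98.95 of lists matched on length and 99.87 on length and expression. Neither match was close. The former had a median log2 CPM of 4.39 against 10.52 for the 29 genes. The latter had 9.43, and a median of 1410 bp against 1128 bp, and longer genes were lower in replicate 3. The list lay at 93.72 among lists matched on both that were drawn from a pool with 27.1% ribosomal protein genes. Sequencing depth is excluded as the whole cause, with 5423 genes called at equal depth. After removal of a smooth trend on GC content, 5601 were called. The GC content was also that of the longest annotated transcript, so these calls cannot show a cause besides GC content. RNA of other cell types is excluded as the whole cause only for cells rich in 8 transcripts chosen after the result was seen. The highest of these 8 in replicate 3, Col1a1, was at 0.572 CPM there. RNA of cells that lack these transcripts was not tested. A difference in RNA integrity, fragment size or culture may remain as an explanation, and no biological explanation was tested, since the design has 1 group.

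Lrrc17, Tmcc2, Fcer2a and a few other genes were called for replicate 1 or 2, some of them for both. The length trend does not account for most of these calls, since all but that of Hist1h2af stayed once it was removed. Mbp was lower in both replicates, at log2 fold changes of -3.10 and -2.86, so replicate 3 is the library that departed in it. The same holds for Hist1h2af, with 1024, 1048 and 2219 counts. Hist1h2ab, with 32, 255 and 300 counts, departed in replicate 1, which also gave its log2 fold change of 0.89 in replicate 3. A shared change of neighbouring genes is excluded for the set, with a median log2 fold change of 0.008 in the called gene's direction, although neighbours of Hist1h2ab and Hist1h2af moved by 0.26 and 0.33 in that direction in replicate 1. No biological explanation was tested, since the design has 1 group.

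Cd38 had 0 counts in each library, and a loss of its genomic region was tested from its neighbours. Fbxl5, 46915 bp before Cd38, was at 33.6, 31.9 and 33.2 CPM, and was the 1 gene within 250 kb at 1 CPM or more in all 3 libraries, and Prom1, 81245 bp after Cd38, had 58, 36 and 61 counts. A loss that reaches both genes on every copy is excluded, since neither was under 36 counts in any library. The nearest genes, Bst1 with 1, 2 and 1 counts and Fgfbp1 with 0, 0 and 1 counts, were near the floor. A loss limited to Cd38 and these nearest genes and a silent gene cannot be told apart. Those genes have too few counts to show whether they are present. No other biological explanation was tested.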
